A study of Mus musculus with 8 samples.

How the data were processed

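Expression was measured on 8 spotted 2-colour arrays of muscle genes. The arrays, named as a human array in the labels, were hybridised with RNA of C2C12, a mouse myoblast line. The cells were kept in control medium (MBN) or in medium conditioned by CAPAN-1, a human pancreatic cancer cell line (MBC). Each of 4 comparisons, MBC14 over MBN14, MBC24 over MBN24, MBC14 over MBN0 and MBC24 over MBN0 (numbers are hours), has an array A with the conditioned RNA in Cy5 and an array B with it in Cy3, per the labels. On array B of MBC14 over MBN0 the description of the labelling names the dyes the other way round from the dye field, which was used. On the other 7 arrays the entries match. The design text says that the same sample and reference RNAs were crossed over both dyes. Arrays A and B were therefore counted as 1 replicate, and the SD over them is technical.

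The deposited values are 1 signed score per spot and array for 9984 spots, with no missing value. How the authors made these scores (background correction, normalisation, scale, log base, standardisation and direction of the ratio) is not given in the sources used here. The scores reach from -23.57 to 24.79, beyond the 16 that a log2 ratio of 16-bit channels can reach, and have nearly one spread on every array, so they resemble standardised ratios. The test plan, written before the data were examined, assumed log2 ratios. It was applied to the scores unchanged, so a value of 1 is 1 score unit and no fold changes are given. Scanner intensities were not used here. Signal over background is thus unknown, no dim spot was left out, and gene lists could not be matched on expression. The number of arrays limits the precision.

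Each array was centred on its median. Gene symbols came from the platform annotation of 2016: 6610 spots list 1 gene, 106 list several and were not named, and 3268 are unnamed here. Spots of one gene were averaged to 2922 genes. Of these, 281 have more than 2 spots, so their spots come from different clones or further copies. The annotation names human genes, while the RNA is from mouse, so a spot can bind the mouse counterpart or a related transcript.

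Orientation followed a rule set before the data were examined. If the 2 arrays of a pair correlate below 0 in most pairs, the scores are read as Cy5 over Cy3 and array B is turned. All 4 pairs did, so this Cy5-over-Cy3 reading is the main one. In the alternative, the conditioned-over-control reading, both arrays are taken as already turned. The spread left over in one reading is the signal of the other. Both are printed because the labels do not settle the choice. A positive value is read as higher in conditioned medium in both, which is likely from the labels' Test and Reference channels. If the scores were reference over test, every sign would turn.

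No test exists for a single comparison. A gene passed the size rule if its mean over the 2 arrays was at least 1 score unit in size and each array gave at least 0.5 in that direction. The count was set beside 1000 shuffles of the genes of array B, and beside the count of the difference between the arrays divided by their number, which equals the count of the other reading. Because array B was turned on a correlation below 0, an excess over the shuffles in the single comparisons follows from that choice. List medians were placed among those of 10000 random lists of the same size. The only test of conditioned medium was limma (version 3.58.1 in R 4.3.3) on 2 values per gene, the array-averaged scores of MBC14 over MBN14 and of MBC24 over MBN24, which share no RNA. It asked for a shift from 0 common to both hours, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Nothing says that further cultures were grown, so its p-values measure only the spread between these 2 values. The remaining comparisons (MBN14 over MBN0, MBN24 over MBN0, MBC24 over MBC14, and the effect at 24 h minus that at 14 h) were derived by subtraction within each array letter. They are indirect, and differences of standardised scores are only roughly additive.

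The 25 gene lists were fixed before the data were examined. 22 had at least 5 measured genes and were tested with limma's fry, beside camera at its preset and at an estimated correlation. No mitochondrially encoded gene was among the named genes. The ribosomal list was taken by symbol prefix and also holds RPS6KA1, RPS6KL1 and RPS19BP1, which are not ribosomal proteins. Named genes followed a rule set beforehand. It takes the 8 highest and 8 lowest genes past the size rule per comparison, up to 10 each way in the matched-hour test in order of p, up to 4 members per list by the size of their matched-hour mean, and 5 each way per derived comparison. Members of a list named for another reason were chosen after their values were seen, and the text says so.

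On simulated data of 2922 genes, the matched-hour limma fit recovered 20% of 50 genes shifted by 1 score unit, 90% at 2 and 100% at 4, with 5 false calls. The size rule recovered 48% at 1 and 100% at 2. Its simulated arrays carried far less noise than the measured ones, whose adjacent spots had an SD of 0.81 to 1.24 score units. These rates therefore do not hold for the data. fry did not call the ribosomal list even when all its genes were shifted by 4 score units, so with 2 values per gene a fry result below the threshold could hardly occur here. camera at its preset correlation called that list at a shift of 0.5. Alternatives were the size threshold, centring, scaling, the handling of spots, leaving out each array letter and the sign of array B. For the matched-hour fit they were also all 4 comparisons, a robust prior, and the array letter as a fixed term with the comparison as a random block. Centring on the running median of 51 or 11 neighbouring spots was added after seeing the data. Neighbouring spots are those next to each other in the deposited order, as the layout of the slide was not used. Figures were drawn with matplotlib.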

Results

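Gene expression of C2C12 mouse myoblasts was compared between medium conditioned by CAPAN-1 pancreatic cancer cells and control medium, at 14 and 24 h and against control medium at 0 h. The question, as known of the study, was how tumour-derived factors alter glucose metabolism and protein breakdown in muscle cells. There were 4 comparisons with 2 dye-swapped arrays each, 8 arrays in all. Over the 8 arrays the median deposited score lay between -0.06 and 0.10 and the SD between 1.34 and 1.58. The 2 adjacent spots of each probe correlated between 0.33 and 0.69 within an array, and their SD was 0.81 to 1.24 score units, so single spots carried technical error of about the size of the thresholds used.

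The orientation of the scores was examined first. As deposited, arrays A and B correlated across 2922 genes at -0.13 in MBC14 over MBN0, -0.27 in MBC24 over MBN0, -0.32 in MBC14 over MBN14 and -0.28 in MBC24 over MBN24. Genes are not independent replicates, so these are descriptions. Under the rule set beforehand, array B was turned and the scores were read as Cy5 over Cy3. The direction of the scores is not settled. Every signed value below is given for this reading, with the conditioned-over-control reading, in which both arrays stay as deposited, beside the main results. Turning array B on a correlation below 0 fixes that more genes pass the size rule than after shuffling. At 14 h matched, 581 genes passed against 368 shuffled, and 186 against 369.7 in the other reading. At 24 h matched these were 515 against 349.7, and 176 against 344.5. Such an excess is therefore no evidence of an effect of the medium.

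**Figure D1:**
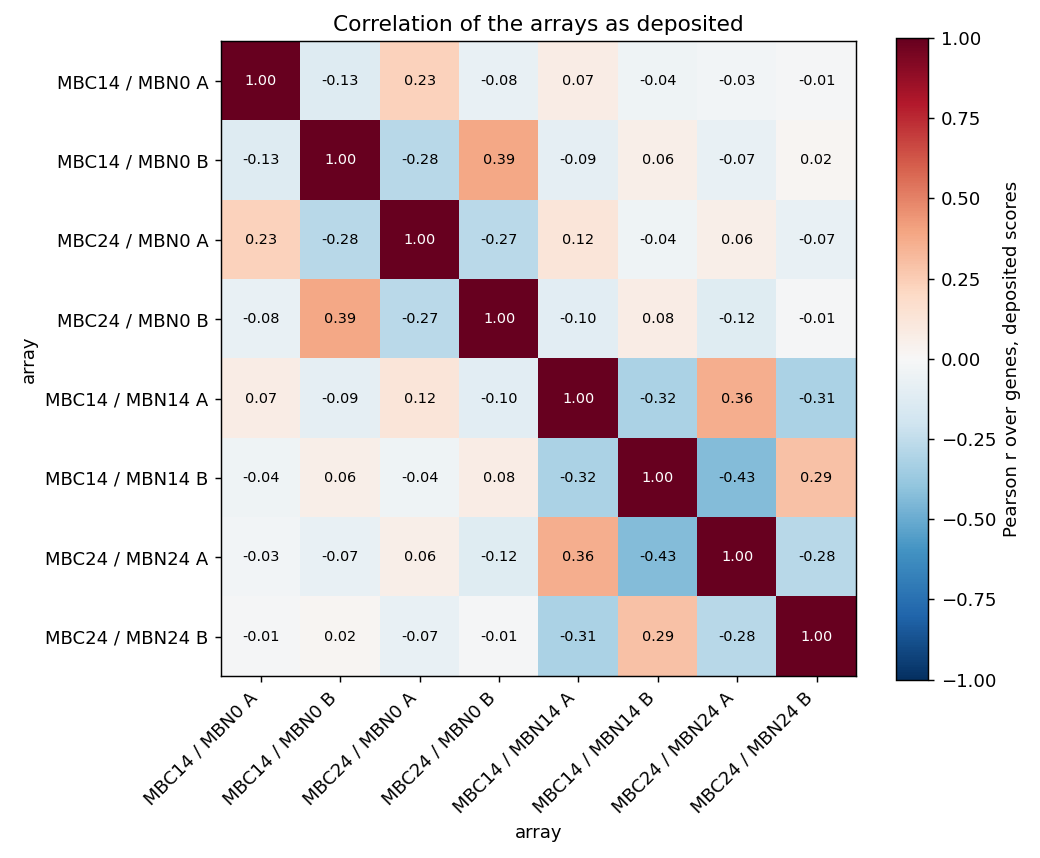
Pearson correlation of deposited scores between the 8 arrays across 2922 genes (rows and columns are arrays, colour and printed value are r). Arrays of the same letter correlate above 0 within the 0 h comparisons (0.23 and 0.39) and within the matched-hour comparisons (0.36 and 0.29), and arrays of opposite letters correlate below 0 there.

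At 14 h in conditioned against control medium (MBC14 over MBN14), 266 genes were higher and 315 lower past the size rule, 19.9% of 2922. GPC1, a cell surface heparan sulfate proteoglycan, had the highest mean score, 4.65 ± 2.43 (SD, n = 2 arrays here and for each ± below). It was followed by ROMO1, a mitochondrial membrane protein (4.64 ± 3.60), the ribosomal protein RPS16 (4.56 ± 1.55), the clathrin adaptor subunit AP2S1 (4.54 ± 2.39), TOR1A (4.51 ± 4.11), the alpha globin HBA2 (4.46 ± 3.95), the dynein regulator PAFAH1B1 (4.37 ± 3.27) and ABTB2 (3.58 ± 3.01). The lowest were the Golgi protein YIPF3 (-4.67 ± 4.01), the elongation factor ELOF1 (-4.42 ± 4.35), the SNARE protein VAMP5 (-3.08 ± 3.64), LITAF (-2.87 ± 0.52), LONRF1 (-2.79 ± 0.79), the centromere protein CENPT (-2.79 ± 1.89), the ARF exchange factor CYTH2 (-2.75 ± 2.04) and the spliceosome component SNRPE (-2.65 ± 2.83). Read as conditioned over control, 104 genes were higher and 82 lower, led by the splicing factor PRPF3 (2.99 ± 2.63) and TSPYL2 (2.43 ± 1.79) at one end and by PRRC2A (-2.79 ± 2.62) and TRIOBP (-2.35 ± 2.17) at the other.

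At 24 h (MBC24 over MBN24), 232 genes were higher and 283 lower. The balance depended on the settings, with 120 higher and 73 lower at a threshold of log2 of 3, 244 and 220 after centring on 51 neighbouring spots, and 181 and 166 on 11. The muscle fructose-bisphosphatase FBP2, an enzyme of gluconeogenesis and glycogen synthesis from lactate, was highest at 4.54 ± 1.36. Next came the nuclear lamin LMNB1 (4.31 ± 1.78), AP2S1 (3.96 ± 2.64), GPC1 (3.95 ± 3.28), the phosphatase subunit PPP2CA (3.90 ± 2.05), SELENOM (3.67 ± 2.70), the survival protein BCL2A1 (3.61 ± 0.32) and the dynein light chain DYNLT1 (3.61 ± 1.20). The lowest were the membrane-bending protein BIN1 (-4.09 ± 4.85), complement C4B (-3.77 ± 3.49), SMAP1 (-3.55 ± 2.77), NUDT3 (-3.26 ± 3.52), PHPT1 (-3.24 ± 1.64), RAB2A (-3.08 ± 1.73), HLA-DRB1 (-2.95 ± 2.64) and MZT2B (-2.95 ± 0.26). Read as conditioned over control, 108 genes were higher and 68 lower. There, CD48 (3.68 ± 4.07), S100A6 (2.47 ± 1.58) and the ribosomal proteins RPS3A (2.60 ± 1.19), RPLP1 (2.48 ± 2.43) and RPL35A (2.42 ± 0.54) were among the highest, and the phosphatase DUSP1, an early response gene, was lowest (-4.05 ± 0.91). ELOF1 was low in both readings at 24 h (-2.37 and -3.42), which means that array A carried most of its signal.

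The shift common to both hours was tested with limma on the 2 matched-hour values (n = 2). In the Cy5-over-Cy3 reading 90 genes rose and 62 fell in conditioned medium at an adjusted p under 0.05. The rises with the lowest p were AP2S1 (4.25 ± 0.39, SE), GPC1 (4.30 ± 0.40), LMNB1 (3.91 ± 0.40), HBA2 (3.97 ± 0.41), PPP2CA (3.68 ± 0.39), the leukocyte tetraspanin CD37 (3.28 ± 0.38), ARGLU1 (3.22 ± 0.39), spermine synthase SMS (3.22 ± 0.40), SELENOM (3.25 ± 0.41) and ROMO1 (3.76 ± 0.48), with adjusted p from 0.00199 to 0.00534. The falls were LONRF1 (-2.68 ± 0.38), CENPT (-2.66 ± 0.38), MZT2B (-2.70 ± 0.39), ELOF1 (-3.40 ± 0.51), NUDT3 (-2.76 ± 0.42), CYTH2 (-2.53 ± 0.39), UACA (-2.48 ± 0.38), LITAF (-2.48 ± 0.40), YIPF3 (-3.35 ± 0.57) and the translation initiation helicase EIF4A1 (-2.21 ± 0.38), with adjusted p from 0.00774 to 0.0154. Array B of MBC24 over MBN24 did not share the fall of LONRF1 (-5.88 on array A, 0.75 on array B) or ELOF1 (-5.79 and 1.05), which missed the size rule there. Past the size rule at both hours were 110 genes higher and 85 lower, where independent lists would share 21.1 and 30.5.

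The matched-hour calls rest on the orientation. In the main reading 666 genes had an unadjusted p under 0.05 in limma, where 146.1 were expected by chance. In the conditioned-over-control reading limma called 0 genes, with 91 at an unadjusted p under 0.05 against 146.1 expected by chance, and the smallest adjusted p was 0.522. ELOF1 had that p, with a mean of -3.25 ± 0.39 (SE). By the size rule 8 genes were higher and 5 lower at both hours there, where independent lists would share 3.84 and 1.91. Led by their means, the former were H3-3A (1.93 ± 0.40, SE), the prolyl isomerase PPIA (1.89 ± 0.38), RPLP1 (1.86 ± 0.46), TMSB10 (1.62 ± 0.43) and HCG27 (1.36 ± 0.38). The latter were DUSP1 (-3.03 ± 0.57), TRIOBP (-2.76 ± 0.42), RAB7A (-1.93 ± 0.40), ODF2 (-1.50 ± 0.42) and TMED2 (-1.25 ± 0.39), and none of these 10 passed (adjusted p 0.921 to 0.995). The 152 calls of the main reading became 86 with arrays entered singly, the array letter as a fixed term and the comparison as a random block. They became 9 with all 4 comparisons in the fit (3 higher and 6 lower), and 0 without the A arrays (303 genes at an unadjusted p under 0.05). Without the B arrays 128 genes were called. After centring on 11 neighbouring spots, 2 were left.

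**Figure D2:**
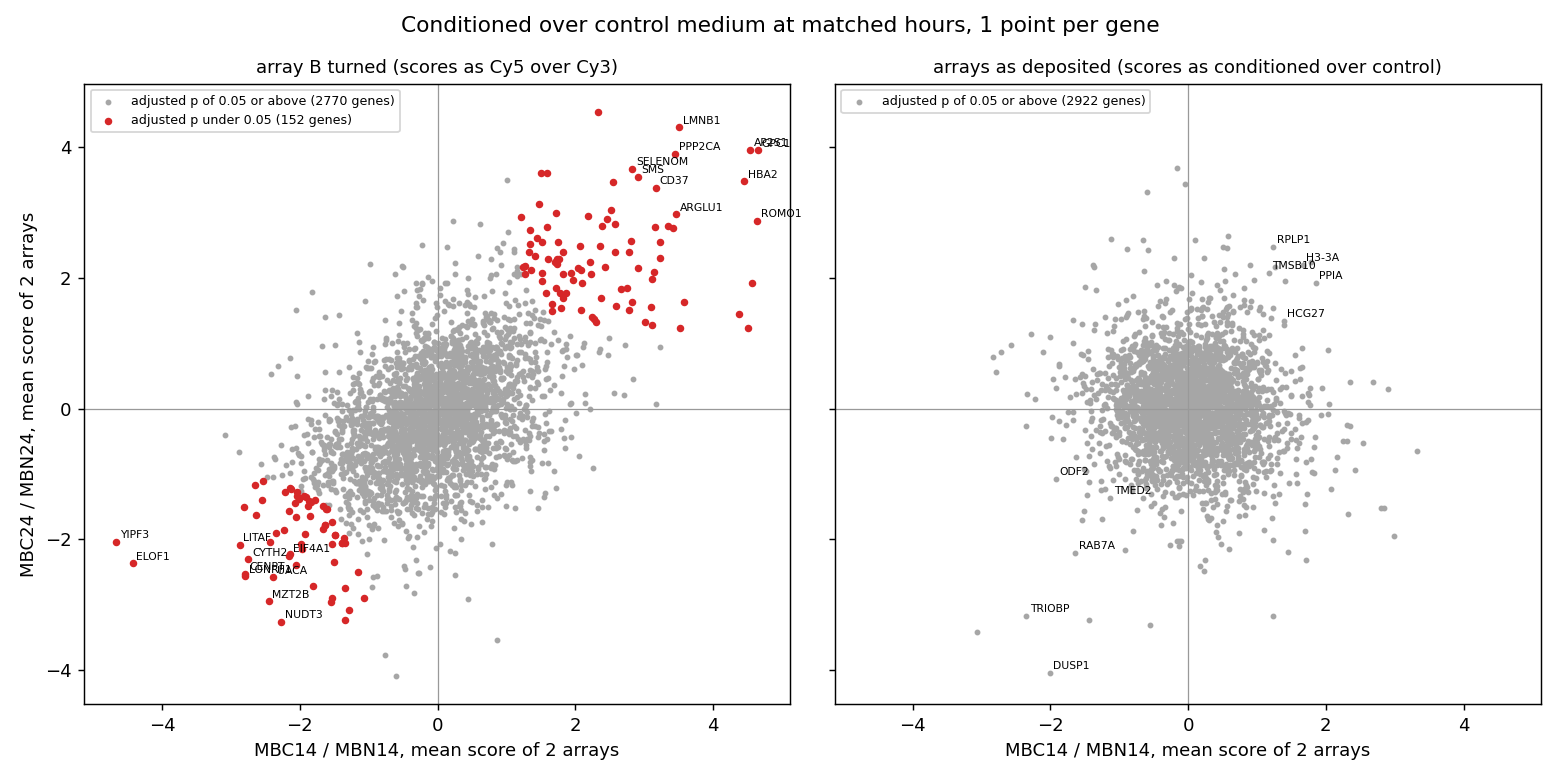
Mean score of each gene over the 2 arrays at 14 h (x axis) and 24 h (y axis) in score units, in the Cy5-over-Cy3 reading (left) and the conditioned-over-control reading (right). Red points are the 152 genes with an adjusted p under 0.05, and the named genes are labelled. The cloud is tilted on the left (r = 0.53) and round on the right (r = -0.06).

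Genes of glucose use were examined next, in the Cy5-over-Cy3 reading unless stated. Of 20 measured genes of glycolysis and glycogen, 0 passed the matched-hour test over all genes and 0 adjusted over the list alone. Here and below, adjusting over the list alone involves no correction for the number of lists. The members with the largest means included PGK1 (1.29 ± 0.44, SE, adjusted p = 0.125 in limma), ALDOA (0.99 ± 0.40) and HK1 (0.97 ± 0.40), and 14 of 20 were above 0. The list median was 0.32 at 14 h and 0.49 at 24 h. The latter lay above 99.55% of random lists, while the conditioned-over-control reading gave 0.14 and -0.06. After centring on 51 and 11 neighbouring spots the 24 h median fell to 0.25 and 0.23. At 24 h LDHA, the lactate dehydrogenase A chain, scored 1.55 ± 1.21 (but -0.30 at 14 h) and ALDOA 1.31 ± 0.80 past the size rule. At 14 h PGK1 (1.98 ± 1.56), ALDOC (1.07 ± 0.74) and the glycogen synthase GYS1 (1.25 ± 0.03) passed it. FBP2, which is not in the list, passed the matched-hour test over all genes (3.43 ± 0.53, SE, adjusted p = 0.00904 in limma). Its 24 h score was -0.96 in the conditioned-over-control reading. By subtraction, FBP2 was among the lowest genes in control medium at 24 h against 0 h in the main reading. That derived fall was larger than its matched rise at 24 h, so FBP2 scored below 0 in MBC24 over MBN0. Some of these were chosen after their values were seen. In the insulin and glucose uptake list 1 of 16 genes passed over all genes and 1 adjusted over the list alone, and that gene was IGFBP2 (1.79 ± 0.38, adjusted p = 0.0334). AKT1 scored 1.10 ± 0.44, EIF4EBP1 1.11 ± 0.39 and GSK3A -1.17 ± 0.39.

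In mitochondrial metabolism, 0 of 19 genes of the TCA cycle and pyruvate dehydrogenase passed over all genes and 2 adjusted over the list alone. IDH3B scored 1.85 ± 0.48, SUCLG1 1.39 ± 0.38, IDH2 -1.14 ± 0.38 and MDH2 1.06 ± 0.40. Of 72 nuclear genes of oxidative phosphorylation, 2 passed over all genes and 0 adjusted over the list alone. Both were ATP synthase subunits, ATP5PF (2.04 ± 0.44, adjusted p = 0.0342) and ATP5MK (1.67 ± 0.40, adjusted p = 0.0475), while ATP5F1B (-1.76 ± 0.47) and NDUFB7 (-1.59 ± 0.40) did not pass. Of 22 genes of fatty acid metabolism 0 passed over all genes and 3 adjusted over the list alone, with ECHS1 at 1.55 ± 0.39, the fatty acid transporter CD36 at 1.48 ± 0.41 and HADHB at -1.38 ± 0.38.

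In protein breakdown, TRIM63, the muscle ubiquitin ligase MuRF1 that is induced in atrophy, rose by 2.57 ± 0.40 (SE, adjusted p = 0.00956), with 2.19 ± 0.10 at 14 h and 2.95 ± 0.04 at 24 h. Its relative TRIM55 rose (1.79 ± 0.39, adjusted p = 0.0342) and the ubiquitin-conjugating enzyme UBE2S fell (-1.69 ± 0.39, adjusted p = 0.0397). These were the 3 of 21 genes of the ubiquitin list that passed over all genes, and 3 passed adjusted over the list alone. The ubiquitin-activating enzyme UBA1 scored -1.24 ± 0.43. The list median at 24 h was -0.55, above 2.47% of random lists (-0.18 and -0.50 after centring on 51 and 11 neighbouring spots), so most members lay on the other side of 0 from TRIM63. Against control medium at 0 h, TRIM63 scored -0.51 at 14 h and -0.40 at 24 h in this reading, and 1.04 and 1.06 in the conditioned-over-control reading. In the latter its matched-hour values were -0.07 ± 3.10 and 0.03 ± 4.18 (SD), so its rise is absent there. Of 22 proteasome genes 1 passed over all genes, the assembly chaperone PSMG1 (1.70 ± 0.41, adjusted p = 0.0475), and 5 adjusted over the list alone. The regulatory subunits went both ways, with PSMD9 at 1.86 ± 0.47, PSMD2 at 1.59 ± 0.41 and PSMD4 at -1.40 ± 0.38. Of 24 genes of lysosome, autophagy and calpain 1 passed over all genes and 1 adjusted over the list alone, the proton pump subunit ATP6V0E1 (1.82 ± 0.41, adjusted p = 0.0369). The calpain inhibitor CAST scored -1.27 ± 0.38, GABARAP -1.14 ± 0.39 and SQSTM1 1.08 ± 0.40.

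Among muscle genes, 3 of 39 sarcomere genes passed over all genes and 3 adjusted over the list alone. The light chain MYL2 rose (2.30 ± 0.47, adjusted p = 0.0266), the slow troponin C gene TNNC1 rose (2.20 ± 0.48, adjusted p = 0.0353) and XIRP1 fell (-1.70 ± 0.40, adjusted p = 0.0432). TNNI1 scored 1.31 ± 0.39. Of 9 genes of myogenic regulation 0 passed over all genes and 5 adjusted over the list alone. The inhibitor of differentiation ID3 scored 1.78 ± 0.44, CDKN1C -1.46 ± 0.39, IGF2 1.33 ± 0.42 and the myogenic factor MYOD1 1.13 ± 0.40. Of 18 genes of calcium handling and excitation 0 passed over all genes and 0 adjusted over the list alone, with the sodium channel SCN4A at -1.70 ± 0.47. In extracellular matrix and adhesion, 3 of 27 genes passed over all genes and 4 adjusted over the list alone. The metalloproteinase inhibitor TIMP1 (2.36 ± 0.44, adjusted p = 0.0196), the muscle protein melusin, ITGB1BP2 (2.28 ± 0.39, adjusted p = 0.0152), and the integrin ITGA7 (2.22 ± 0.43, adjusted p = 0.0232) rose, and TNC scored 1.37 ± 0.38. The list median of 0.36 at 24 h lay above 99.18% of random lists, against -0.03 in the conditioned-over-control reading, and was 0.41 and 0.59 after centring on 51 and 11 neighbouring spots.

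In protein synthesis and folding, 4 of 39 chaperone and endoplasmic reticulum stress genes passed over all genes and 9 adjusted over the list alone. The chaperonin subunits CCT3 (2.54 ± 0.40, adjusted p = 0.00993) and CCT2 (2.15 ± 0.40, adjusted p = 0.0212) and DNAJC7 (2.23 ± 0.38, adjusted p = 0.0152) rose, and the endoplasmic reticulum chaperone HSP90B1 fell (-1.75 ± 0.38, adjusted p = 0.0342). The list median was -0.44 at 24 h, above 1.74% of random lists, and became 0.01 after centring on 11 neighbouring spots. Of 39 translation factors 3 passed over all genes and 5 adjusted over the list alone. EIF4A1 and EIF4G1 (-1.93 ± 0.41, adjusted p = 0.0311) fell and EEF2 rose (1.87 ± 0.42, adjusted p = 0.037). The list median of -0.43 at 24 h lay above 2.15% of random lists, and was -0.25 and -0.22 after centring on 51 and 11 neighbouring spots. Of 69 ribosomal protein genes 3 passed over all genes and 4 adjusted over the list alone. RPS16 rose (3.25 ± 0.58, adjusted p = 0.0174), RPL7 (-1.75 ± 0.38, adjusted p = 0.0342) and RPL22 (-1.71 ± 0.39, adjusted p = 0.0387) fell, and RPL6 scored -1.62 ± 0.40. The ribosomal list median at 24 h was -0.43, above 0.37% of random lists, and 0.52 in the conditioned-over-control reading. After centring on 51 and 11 neighbouring spots the former was -0.08 and -0.06. As deposited, the ribosomal median was 0.25 on array A and 0.88 on array B. Once array B was turned, the arrays therefore went opposite ways, and -0.43 is a value on which they did not agree.

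In the stress and signalling lists, S100A8 rose (1.80 ± 0.39, adjusted p = 0.0342) and IFITM1 fell (-1.57 ± 0.38, adjusted p = 0.0476), the 2 of 11 inflammatory genes that passed over all genes, and 3 passed adjusted over the list alone. NFKB2 scored -1.78 ± 0.53. Of 11 cell cycle genes 0 passed either way, with TUBB at -1.22 ± 0.39 and STMN1 at 1.14 ± 0.38. Of 21 genes of oxidative stress 0 passed either way, with PRDX6 at -1.30 ± 0.38, and of 5 hypoxia genes 0 passed over all genes and 2 adjusted over the list alone, with DDIT4 at -1.07 ± 0.38. Markers of cell types other than myoblasts were examined as well. Of 10 blood cell genes 2 passed over all genes and 3 adjusted over the list alone, HBA2 upward and HLA-DRB1 downward (-2.25 ± 0.45, adjusted p = 0.0236). The other alpha globin HBA1, looked up after the values were seen, did not share the rise of HBA2 (-0.45 ± 0.46, adjusted p = 0.604 in limma). In MBC14 over MBN0 the order was reversed, with 2.95 for HBA1 and -0.31 for HBA2. Of 6 endothelial genes 1 passed over all genes and 1 adjusted over the list alone, CLDN5 (-1.86 ± 0.39, adjusted p = 0.0301). Of 9 fibroblast and smooth muscle genes 0 passed over all genes and 1 adjusted over the list alone, with S100A4 at -1.50 ± 0.39 and TAGLN at -1.14 ± 0.38. Of 4 adipocyte genes 0 passed either way, with RBP4 at -1.21 ± 0.39. The 2 measured epithelial markers, SPINT2 (0.13 ± 0.39) and S100P (0.09 ± 0.40), did not pass either.

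As whole lists, limma's fry called 0 of 22 in the Cy5-over-Cy3 reading, and camera called 0 with its preset and 0 with an estimated correlation. The lowest fry p was that of the translation factors (adjusted p = 0.251). At an unadjusted p under 0.05, fry had 2 lists, these and the cell cycle genes, and camera at its preset correlation had 2, extracellular matrix and glycolysis. With 2 values per gene fry also missed a shift of 4 score units in simulated data, so its count of 0 carries no weight. In the conditioned-over-control reading camera at its preset correlation called the ribosomal proteins, with 53 of 69 genes above 0 and a median of 0.42 (adjusted p = 5.87e-05). It was not called with an estimated correlation (adjusted p = 0.983). At 24 h, 6 of 22 lists of the main reading lay outside the central 95% of random lists, where 1.1 would by chance, and at 14 h 0 did. The conditioned-over-control reading had 1 at 24 h and 1 at 14 h.

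**Figure D3:**
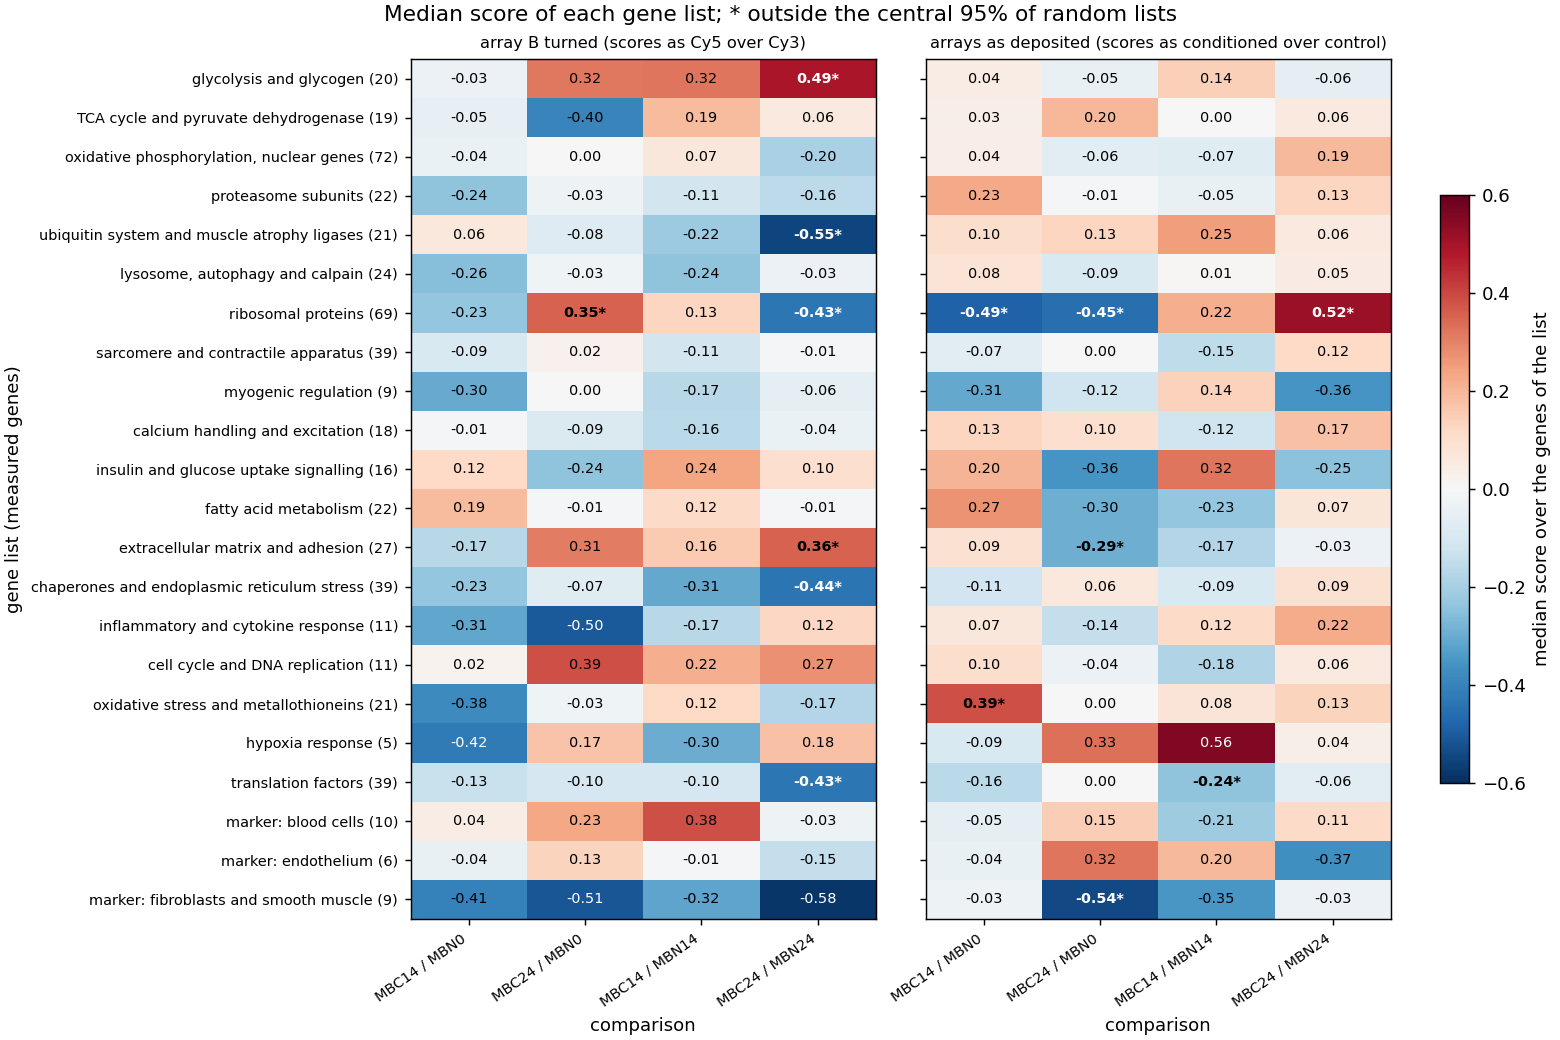
Median score over the genes of each of 22 lists (rows) in the 4 comparisons (columns), in the Cy5-over-Cy3 reading (left) and the conditioned-over-control reading (right). Stars mark medians outside the central 95% of 10000 random lists. Ribosomal proteins carry -0.49, -0.45 and 0.52 on the right, and glycolysis 0.49 on the left.

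The ribosomal protein genes had medians outside the range of random lists on 6 of the 8 arrays as deposited, without any turning. On array A their median was -0.88 in MBC14 over MBN0, -0.26 in MBC24 over MBN0, 0.28 in MBC14 over MBN14 and 0.25 in MBC24 over MBN24. The matched-hour medians of array A lay only just above the range, whose upper bounds were 0.27 and 0.23. On array B the medians were -0.53, -0.77, 0.05 and 0.88. In the conditioned-over-control reading, 12 of 69 were lower and 1 higher past the size rule in MBC14 over MBN0, 13 lower and 2 higher in MBC24 over MBN0, 3 higher and 2 lower in MBC14 over MBN14 (median 0.22, within the central 95% of random lists), and 12 higher and 0 lower in MBC24 over MBN24. The last 12 included RPS3A (2.60 ± 1.19), RPL35A (2.42 ± 0.54), RPS12 (2.19 ± 0.39) and RPL7A (1.95 ± 1.07), all ± SD with n = 2 arrays. By subtraction, control medium at 24 h against 0 h had a median of -0.92, with 23 lower and 1 higher, and at 14 h of -0.63, with 20 lower and 1 higher. After centring on 51 and 11 neighbouring spots the median fell from 0.52 to 0.21 and 0.20 in MBC24 over MBN24. It went from -0.49 to -0.34 and -0.26 in MBC14 over MBN0, and from -0.45 to -0.41 and -0.29 in MBC24 over MBN0. RPS16 (3.76 in MBC14 over MBN0) went against its list.

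**Figure D4:**
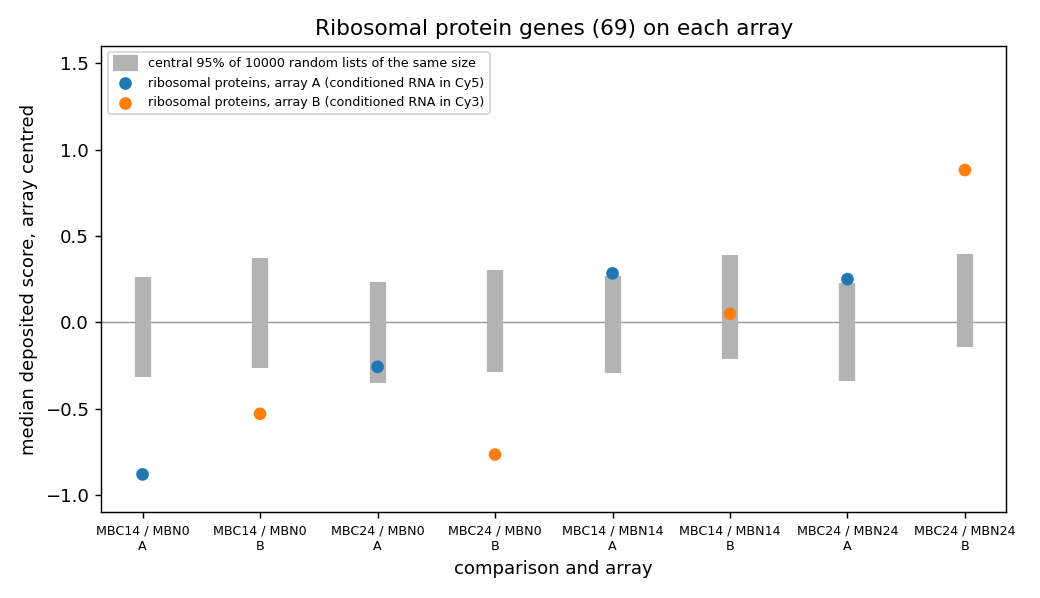
Median deposited score of the 69 ribosomal protein genes on each of the 8 arrays (points, score units), with the central 95% of random lists of that size (bars). The medians lie below the bars on 3 arrays, all with the 0 h control, above them on 3 arrays, all at matched hours, and within them on 2. Array A at both matched hours lies only just above.

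Against control medium at 0 h, 213 genes were higher and 245 lower after 14 h in conditioned medium (MBC14 over MBN0), but 211 and 205 after centring on 51 neighbouring spots, and 192 and 169 on 11. The total of 458 stood against a shuffled mean of 363.3, an excess that follows from turning array B. This comparison joins the medium with time in culture. The ubiquitin ligase RNF5 (3.85 ± 1.98), SUGT1 (3.26 ± 0.37), the mitochondrial aspartate-glutamate carrier SLC25A12 (2.97 ± 0.21), HBA1 (2.95 ± 1.72), the ATP synthase subunit ATP5MC1 (2.82 ± 2.65), CENPT (2.81 ± 2.90), RPL37 (2.78 ± 0.87) and CNPPD1 (2.73 ± 0.46) were highest. The lowest were ACSF2 (-3.42 ± 1.84), the glyoxalase HAGH (-3.37 ± 0.83), YWHAG (-3.26 ± 0.23), the DNA polymerase subunit POLA1 (-2.92 ± 0.63), SCAMP2 (-2.88 ± 1.21), MARK4 (-2.78 ± 1.27), ARL1 (-2.67 ± 0.01) and SLC25A29 (-2.61 ± 0.30). With both arrays as deposited, 164 were higher and 138 lower, with RPS16 (3.76 ± 0.20) and FGFBP2 (2.92 ± 2.60) at the top, and NPM1 (-2.73 ± 1.89), the cardiac actin ACTC1 (-2.71 ± 1.40) and RPS12 (-2.47 ± 0.41) among the lowest. No list lay outside the central 95% of random lists in the main reading.

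After 24 h (MBC24 over MBN0), 245 genes were higher and 318 lower. The total of 563 stood against a shuffled mean of 357.3, which again follows from turning array B. The Notch ligand JAG2 (3.64 ± 1.59), RPL37 (3.16 ± 1.39), the replication factor MCM3 (2.87 ± 0.05), ALOX5AP (2.84 ± 1.54), GSDMC (2.73 ± 0.59), PHLDB2 (2.64 ± 2.63), ACIN1 (2.53 ± 0.29) and SAR1A (2.36 ± 1.16) were highest. ELOF1 (-3.94 ± 0.59), DUSP1 (-3.93 ± 1.38), MARK4 (-3.74 ± 0.23), the chromatin organiser SATB1 (-3.73 ± 0.36), RBBP7 (-3.44 ± 0.93), LITAF (-2.99 ± 0.64), ARHGAP4 (-2.92) and TRIOBP (-2.88 ± 2.91) were lowest. The 69 ribosomal protein genes had a median of 0.35, above 99.98% of random lists, with 14 higher and 7 lower past the size rule. After centring on 51 and 11 neighbouring spots the median was 0.14 and 0.16. As deposited, the ribosomal medians were -0.26 on array A and -0.77 on array B, so the arrays went opposite ways once array B was turned. With both arrays as deposited, 91 were higher and 109 lower, with CTSG (5.47 ± 5.52) highest, NPM1 lowest (-3.42 ± 2.75), and a ribosomal median of -0.45, below all random lists.

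The comparisons were set against each other. In the Cy5-over-Cy3 reading the 2 comparisons with 0 h correlated at 0.40 across genes, but they share MBN0. Simulated RNAs with independent values of equal spread gave 0.50 when all spread lay between RNAs and -0.01 when all lay between arrays. The covariance of the 2 comparisons was 0.304, against 0.386 simulated for the former case. The shared control can give a correlation by itself. The simulation held no effect of medium or time, which could change the values for real RNAs. The 2 matched-hour comparisons share no RNA and correlated at 0.53. MBC14 over MBN0 and MBC14 over MBN14, which share MBC14, correlated at 0.11, and the 24 h pair sharing MBC24 at 0.09, against 0.50 and 0.51 simulated with all spread between RNAs. With both arrays as deposited the same 4 correlations were 0.17, -0.06, 0.00 and -0.10.

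The derived comparisons are indirect. For control medium alone, MBN14 over MBN0 gave 356 genes higher and 355 lower (300 and 338, and 266 and 278, after centring on 51 and 11 neighbouring spots), led by YIPF3 (6.67 ± 4.91), CENPT (5.60 ± 4.79) and the proto-oncogene SET (4.36 ± 2.74), and by ROMO1 (-6.23 ± 3.40), POLA1 (-6.15 ± 2.70) and YWHAG (-5.62 ± 1.66). MBN24 over MBN0 gave 427 higher and 398 lower (360 and 374 after centring on 51 neighbouring spots, 300 and 314 on 11), with the receptor IGF2R (6.22 ± 6.73) and PHPT1 (4.25 ± 0.30) at the top and FBP2 (-6.31 ± 1.85) and PPP2CA (-5.07 ± 4.18) at the bottom. Both a comparison with 0 h and a matched-hour comparison enter each of these values. MBC24 over MBC14 gave 259 higher and 254 lower (215 and 254, and 209 and 248, after that centring), with ARAP1 (8.05 ± 7.25) highest and SATB1 (-4.17 ± 3.35) lowest. The effect at 24 h minus that at 14 h gave 198 higher and 266 lower, with EIF3A (3.60 ± 0.69) highest and SMAP1 (-4.41 ± 3.39) lowest. That total of 464 lay below the shuffled mean of 510.2, at the lowest of 1000 shuffles. It is thus no sign that the effect differed between the hours. For MBN14 over MBN0, MBN24 over MBN0 and MBC24 over MBC14 the totals were 711, 825 and 513, against 591.6, 635.8 and 470.2 shuffled. With both arrays as deposited the 4 derived counts were 235 and 241, 193 and 267, 191 and 231, and 289 and 294. There, MBN14 over MBN0 was led by LRP1 (4.99 ± 6.19), ELOF1 (4.42 ± 4.35) and FITM1 (4.33 ± 4.23), with RHNO1 lowest (-3.41 ± 3.78), and YIPF3 and CENPT had 3.47 and 3.38. MBN24 over MBN0 was led by CTSG (6.14 ± 5.89), with TMSB10 lowest (-4.94 ± 1.57), MBC24 over MBC14 by GRSF1, with HBP1 lowest (-4.35), and the difference in effect by TECR (3.91 ± 1.76), with PRPF3 lowest (-4.94 ± 1.23). The sign turned between the readings for IGF2R (-4.76), FBP2 (1.31) and PPP2CA (2.96) in MBN24 over MBN0, for ARAP1 (-5.13) and SATB1 (2.37) in MBC24 over MBC14, and for EIF3A (-0.49) in the difference in effect.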

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

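All of these results were singled out after the data were seen, and none of the differences named here was tested. In the Cy5-over-Cy3 reading, 3 genes passed the size rule in opposite directions at 14 h and 24 h in conditioned over control medium, where independent lists would give 50.8. EIF3A, a subunit of translation initiation factor 3, scored -1.82 ± 0.76 (SD, n = 2 arrays here and below) at 14 h and 1.78 ± 1.46 at 24 h, a difference of 3.60. ECI2, an enoyl-CoA isomerase of fatty acid oxidation, scored 1.45 ± 1.26 at 14 h and -1.52 ± 0.04 at 24 h, a difference of -2.97. OXSM, a mitochondrial fatty acid synthase enzyme, scored 1.13 ± 0.36 at 14 h and -1.53 ± 1.43 at 24 h, a difference of -2.66. In the conditioned-over-control reading 7 genes passed in opposite directions, where independent lists would give 5.45.

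Spots that the annotation used here does not name were left out of every comparison. Of 1634 such spot pairs, 252 passed the size rule in the same direction at both matched hours, 15.4%, where independent lists would share 74.4. At 14 h 465 of these pairs passed and at 24 h 441. Of the 2922 named genes, 581 passed at 14 h and 515 at 24 h, and 110 passed higher and 85 lower at both hours. The share that passed was thus larger for the unnamed pairs than for the named genes, and why was not tested. A named gene can average several spot pairs, so the shares are not like for like. In the conditioned-over-control reading 12 unnamed pairs passed at both hours, and 8 named genes passed higher and 5 lower.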

How the results depend on the processing

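Counts of the size rule are given for MBC14 over MBN0, MBC24 over MBN0, MBC14 over MBN14, MBC24 over MBN24, MBN14 over MBN0, MBN24 over MBN0, MBC24 over MBC14 and the effect at 24 h minus that at 14 h, in this order. They were 458, 563, 581, 515, 711, 825, 513 and 464. At a threshold of log2 of 1.5 they were 903, 1008, 969, 978, 1059, 1188, 904 and 789, and at log2 of 3 146, 173, 210, 193, 341, 422, 160 and 180. With each probe on its own they were 1341, 1526, 1468, 1385, 1909, 2086, 1585 and 1325 probes, which are not genes and not of the same total. Leaving out an array letter removed the demand that both arrays go one way, which raises the count by construction (lowest to highest of leaving out A or B): 947 to 1015, 960 to 1005, 994 to 1006, 950 to 981, 1357 to 1393, 1432 to 1492, 1023 to 1299 and 1232 to 1242. With the sign of array B as deposited they were 302, 200, 186, 176, 476, 460, 422 and 583, and after centring on 11 neighbouring spots 361, 377, 365, 347, 544, 614, 457 and 399. The other settings (no centring, scaling to one MAD, the median over probes, no minimum per array, 51 neighbours) left every count within 1.5 times the main one.

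The matched-hour test called 152 genes. Leaving out an array letter gave 0 to 128. With the 4 arrays entered singly, the array letter as a fixed term and the comparison as a random block, 86 genes passed, all among the 152. That fit took technical arrays as observations. The correlation of arrays within a comparison (-0.105) came from mean squares, since limma gave none for 4 arrays. The array letters do not pair, as their deviations correlate at -0.06. All 4 comparisons in the fit gave 9, each probe on its own 9, 11 neighbouring spots 2, and array B as deposited 0. fry called 0 lists under the settings run for lists, which leave out each probe on its own and the robust prior, but it could hardly call a list in this design. The mean correlation of A and B was -0.248, and -0.153 with each probe on its own. It was 0.174 without the genes past the size rule, which removes opposed genes by construction. Why the counts and calls differ between the other settings was not tested here.

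Of 124 values of named genes, 55 changed sign when array B was left as deposited, 31 more moved and 10 were weaker. The new values, in score units, were as follows. For MBC14 over MBN0: ACSF2 1.30, YWHAG 0.16, POLA1 0.45, MARK4 0.90, ARL1 0.0062 and SLC25A29 0.21. For MBC24 over MBN0: JAG2 -1.13, RPL37 -0.98, MCM3 -0.036, ELOF1 0.42, DUSP1 0.98, MARK4 0.16, SATB1 0.25, RBBP7 0.66, LITAF 0.45 and TRIOBP 2.06. For MBC24 over MBN24: FBP2 -0.96, LMNB1 -1.26, AP2S1 -1.87, GPC1 -2.32, PPP2CA -1.45, SELENOM -1.91, BCL2A1 -0.22, DYNLT1 -0.85, BIN1 3.43, C4B 2.46, RAB2A 1.22 and HLA-DRB1 1.87. For MBN14 over MBN0: UACA -0.13. For MBN24 over MBN0: IGF2R -4.76, ANXA2 -1.47, FBP2 1.31, PPP2CA 2.96, HBA2 3.63, GPC1 1.57 and NSFL1C 1.18. For MBC24 over MBC14: ARAP1 -5.13, IGF2R -4.28, YWHAG -0.98, HAGH -0.37 and SATB1 2.37. For the effect at 24 h minus that at 14 h: EIF3A -0.49, MATR3 -2.58, TMEM134 -1.16 and TM4SF1 2.11. For the matched-hour mean: AP2S1 -0.090, GPC1 -0.30, LMNB1 -0.14, PPP2CA -0.60, CD37 -0.16, ARGLU1 -0.46, SMS -0.24, SELENOM -0.58, CENPT 0.24 and UACA 0.054. After centring on 11 neighbouring spots 70 of the 124 stayed, 19 were weaker, 35 moved and 0 changed sign. Leaving out an array letter could not move the 104 values of single and derived comparisons, since each array of a pair lies within their SD of the mean by construction. Of the matched-hour means, all 20 were weaker without the A arrays and all 20 stayed without the B arrays. The 51 and 11 neighbouring spots were chosen after the data were seen.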

Other observations

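Camera, the matched-hour test and the mean correlation of A and B before centring, cited again here, belonged to the test plan. The tests of possible causes in this part were chosen after the result was seen, with 1 exception. The prediction for the neighbours of ribosomal spots was written before its result, but the bootstrap bounds by which it was judged were added after.

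In the conditioned-over-control reading the ribosomal protein genes lay outside random lists in 3 of 4 comparisons (camera called them at its preset correlation only, adjusted p = 0.983 at the estimated one), and slide position can be neither held nor excluded as a cause. The prediction took under 25% of the ribosomal median in the neighbouring spots as the value against it, and the largest share was 23.6% (24 h matched), but its bootstrap bounds of 13.1 to 35.2% reach past 25%. After these values were seen, the rule for judging them was changed more than once, and the version kept is the strict one, which asks the whole interval to lie under 25%. A dye bias of abundant transcripts common to all arrays is argued against as the whole cause. In Cy5-over-Cy3 scores it would give all arrays 1 sign, but 3 of 8 lay above the range of random lists and 3 below it. In conditioned-over-control scores it would give arrays of the same letter 1 sign. Array A lay below the range in MBC14 over MBN0 (-0.88) and only just above it at both matched hours (0.28 and 0.25, upper bounds 0.27 and 0.23). The random lists also take genes as independent, so the ranges may be too narrow for this list. Array B lay below it in both 0 h comparisons (-0.53 and -0.77) and above it in MBC24 over MBN24 (0.88). A change in ribosomal protein transcripts with medium and time, or binding of related transcripts, stays open and untested.

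The opposition of arrays A and B, on which the orientation rests, has more than one candidate source. Centring on 11 neighbouring spots left the mean correlation of A and B at -0.174 (-0.248 before), below 0 in all 4 comparisons. This argues against a position effect common to such runs of spots as the whole cause. The runs follow the deposited order and not the slide layout, so slide position in other forms stays open. A dye bias common to all 8 arrays is argued against as the whole cause. The turned means correlated at no more than 0.135 between the 0 h and the matched-hour comparisons. The matched-hour comparisons, which share no RNA, correlated at 0.53. The 0 h comparisons correlated at 0.40, but they share MBN0, which can give a correlation by itself. A group difference in scores that are Cy5 over Cy3 would give the 0.534 between the matched-hour comparisons, but so would a dye bias confined to those slides, and these cannot be told apart. The turned means of the pairs sharing MBC14 or MBC24 correlated at only 0.11 and 0.09. Simulated RNAs with all spread between them gave 0.50 and 0.51, and the 0.135 came from a pair that shares no RNA. The simulated RNAs were independent and held no effect of medium or time, so real RNAs could give other values. Unnamed spot pairs opposed each other too, with A and B correlated at -0.247, -0.254, -0.439 and -0.398 in the 4 comparisons. Named spot pairs gave -0.136, -0.270, -0.323 and -0.272 in the same order. The ribosomal protein genes went against the main orientation. As deposited, their medians had the same sign on arrays A and B in all 4 comparisons. In the same order they were -0.88 and -0.53, -0.26 and -0.77, 0.28 and 0.05, and 0.25 and 0.88. Of these, -0.26 and 0.05 lay within the range of random lists.

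After centring on 11 neighbouring spots, the median size of the 152 genes called at matched hours fell from 2.08 to 1.22 score units, by 41.2% (bootstrap 37.1 to 47.4%), with a median SE of 0.40 before and 0.36 after. The scores shrank while the median SE did not grow. That 149 of 152 kept their direction says little, since these genes were picked for large scores in the same data. How far the scores of uncalled genes shrank was not measured, so slide position and signal cannot be told apart for the 152. Adjacent spot pairs, mostly of different genes, correlated at 0.355 at 14 h and 0.30 at 24 h in the Cy5-over-Cy3 reading, against 0.062 and 0.073 in the other. Whether spots with no target RNA in the culture contribute stays open with so few genes, since 3 of 22 blood, endothelial, adipocyte and epithelial genes passed the test, 13.6% (exact 95% interval 2.91 to 34.9%, exact p = 0.103), against 5.2% of all genes. The blood and endothelial genes alone, pooled first, gave 3 of 16 (18.8%, exact p = 0.0469), and conditioned medium itself stays open too.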
